A study of Homo sapiens with 12 samples.

How the data were processed

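Total RNA from 12 cultures of human induced microglia-like cells was sequenced, 1 library per culture. The groups are named after genotype and treatment: WT and KO (3 libraries each), WT LPS, KO LPS and KO LPS BMS (2 libraries each), where BMS is BMS265246. Groups and replicate numbers were taken from the sample titles. Per the labels, RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit. The authors deposited 1 table of raw read counts per gene, with 1 column per library. Its values were whole numbers, and the table held 57992 Ensembl gene IDs, of which 24552 had no count in any library. The labels name CASAVA 1.7, Cufflinks and the genome build GRCh38. The aligner, the read counter, the strand setting and the annotation release are not given in the sources used here. Gene symbols were available for 56948 IDs from a table of gene names and for 440 more from GENCODE release 29, and 604 IDs had none. Positions were taken from GENCODE release 29, which held 57388 of the IDs.

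The total count per library ranged from 13888283 to 17639136. A count of 0 allows up to 3 counts, which corresponds to 0.154 to 0.236 CPM on TMM-scaled libraries, and such floors cover counting error only, since PCR copies of 1 molecule are not independent. The most abundant gene took 1.21% to 1.58% of the counts in 11 libraries (FTL), and 1.17% in WT LPS replicate 2 (SOD2). Mitochondrially encoded transcripts took 1.03% to 1.69%. Between replicates of a group, the Pearson correlation of log2 CPM across genes, which are not independent replicates, was 0.993 to 0.997. The chi-square per degree of freedom of their counts was 2.1 to 7.65, and 12.25 for the pair of KO LPS libraries.

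Genes were kept by edgeR's filterByExpr with the group factor, which left 16022. Library sizes were scaled by TMM, with factors from 0.872 to 1.117. edgeR 4.0.16 in R 4.3.3 fitted all 12 libraries with 1 mean per group (quasi-likelihood, robust), and the common biological coefficient of variation was 0.064. Comparisons were tested with edgeR's quasi-likelihood F test, 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 7 comparisons were KO vs WT, WT LPS vs WT, KO LPS vs KO, KO LPS vs WT LPS, the genotype by LPS interaction, KO LPS BMS vs KO LPS, and KO LPS BMS vs KO. Standard errors were those of the fitted log2 fold changes. Groups of 2 libraries borrow their spread from all groups of the fit. An exact permutation test of 3 against 3 libraries could not give a p under 0.1, and 2 against 2 could not give a smaller one. In data simulated from the fit with known changes, the KO vs WT test found 64.2% of genes changed by 1.5-fold, 82.1% of those changed by 2-fold and 95.5% of those changed by 4-fold, with 10 false calls among 183 (5.5%). For KO LPS BMS vs KO LPS these shares were 55.2%, 80.6% and 87.9%, with 7 false calls among 168, and for the interaction 40.3%, 64.2% and 93.9%, with 9 among 145. The highest share of false calls was 7.4% (13 of 176, WT LPS vs WT), above the nominal 5%.

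Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the 41 lists of a comparison. Each list was also tested with an estimated correlation, and with fry, which asks whether its genes move, on balance, 1 way and does not compare them with other genes. A list median is the median log2 fold change of its tested members. The lists covered homeostatic and disease-associated microglial genes, pro-inflammatory cytokines, chemokines, NF-kB genes, type I interferon-stimulated and interferon-gamma-type genes, LPS receptor and TLR signalling, inflammasome, anti-inflammatory genes, MHC class I and II, phagocytosis and lysosome, G1/S, G2/M, CDKs and cyclins, p53 targets, histones, immediate early genes, the MEF2 family and myeloid transcription factors. They also covered glycolysis, oxidative phosphorylation, cholesterol synthesis, LXR targets, the unfolded protein response, oxidative stress, extracellular matrix, kynurenine and prostaglandin enzymes, heat shock and mitochondrially encoded transcripts. Markers of 10 other cell types completed them. Some genes stand in several lists, such as NLRC5 and IL1B.

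The tests, the 41 lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from those said to be added later. In each comparison the named genes were MEF2C, the 6 largest called rises and falls with a mean of at least 5 CPM, a symbol and groups that do not overlap, the 2 called members with the lowest adjusted p per direction of each list that camera called or of which at least 1 in 4 was called, and a panel of 13 genes. The text gives part of them. For overlaps between comparisons, the count expected for independent lists was computed from the numbers called, and 10 data sets without any effect were simulated with the same shared libraries. Alternatives were DESeq2 1.42.0 size factors, library size only, upper-quartile factors, no filter on low counts, a filter of 5 CPM in 2 libraries, the DESeq2 Wald test, limma-voom, only the libraries of the 2 groups compared, the replicate number as a block, other thresholds, and leaving out each library in turn. Scripts ran in Python 3.11.15 and figures were drawn with matplotlib 3.10.9.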

Results

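RNA sequencing measured gene expression in 12 libraries of induced microglia-like cells (iMGLs), cells resembling the resident macrophages of the brain that were differentiated from the H1 human pluripotent stem cell line. The cells were unedited (WT) or carried a knockout (KO) of MEF2C, a transcription factor of the MEF2 family that is expressed in microglia. Lipopolysaccharide (LPS), a component of the bacterial cell wall that is sensed through TLR4, was the stimulus, and BMS265246, named BMS in the labels and described in the series title as an inhibitor of the kinase CDK2, was the compound. There were 3 WT and 3 KO libraries without LPS, and 2 libraries each of WT cells with LPS, KO cells with LPS, and KO cells with LPS and BMS. No library held WT cells with the compound, and none held the compound without LPS. The doses and times of treatment are not given in the sources used here. The labels call the replicates biological replicates of 1 cell line, so the p-values measure variation between such cultures and not between donors or knockout clones.

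A count of 0 in 1 library allowed a level of up to 0.154 to 0.236 CPM (counts scaled to a common library size by TMM), a bound that covers counting error only. Expression levels are normalised read counts in CPM, given as mean ± SD over 3 libraries for the groups without LPS and over 2 for the others. Changes are log2 fold changes ± SE with adjusted p from edgeR's quasi-likelihood test over 16022 genes, and positions are those of GENCODE release 29 on GRCh38. List counts are of tested members, and list medians are of log2 fold changes.

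MEF2C (ENSG00000081189, chromosome 5, 88717117 to 88904257) was still transcribed in KO cells. Its level was 193 CPM, 183 CPM and 177 CPM in the 3 WT libraries and 136 CPM, 129 CPM and 135 CPM in the 3 KO libraries, so that every KO library lay below every WT library. The mean fell from 184 ± 7.86 to 133 ± 4.01 CPM, a log2 fold change of -0.47 ± 0.05, adjusted p = 4e-07. With LPS the level was 49.6 CPM and 51.6 CPM in WT, 45.9 CPM and 46.8 CPM in KO, and 43.7 CPM and 44.1 CPM in KO cells with the compound. The kind of edit is not given in the sources used here, and gene counts do not show whether the remaining transcripts encode a protein.

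**Figure D1:**
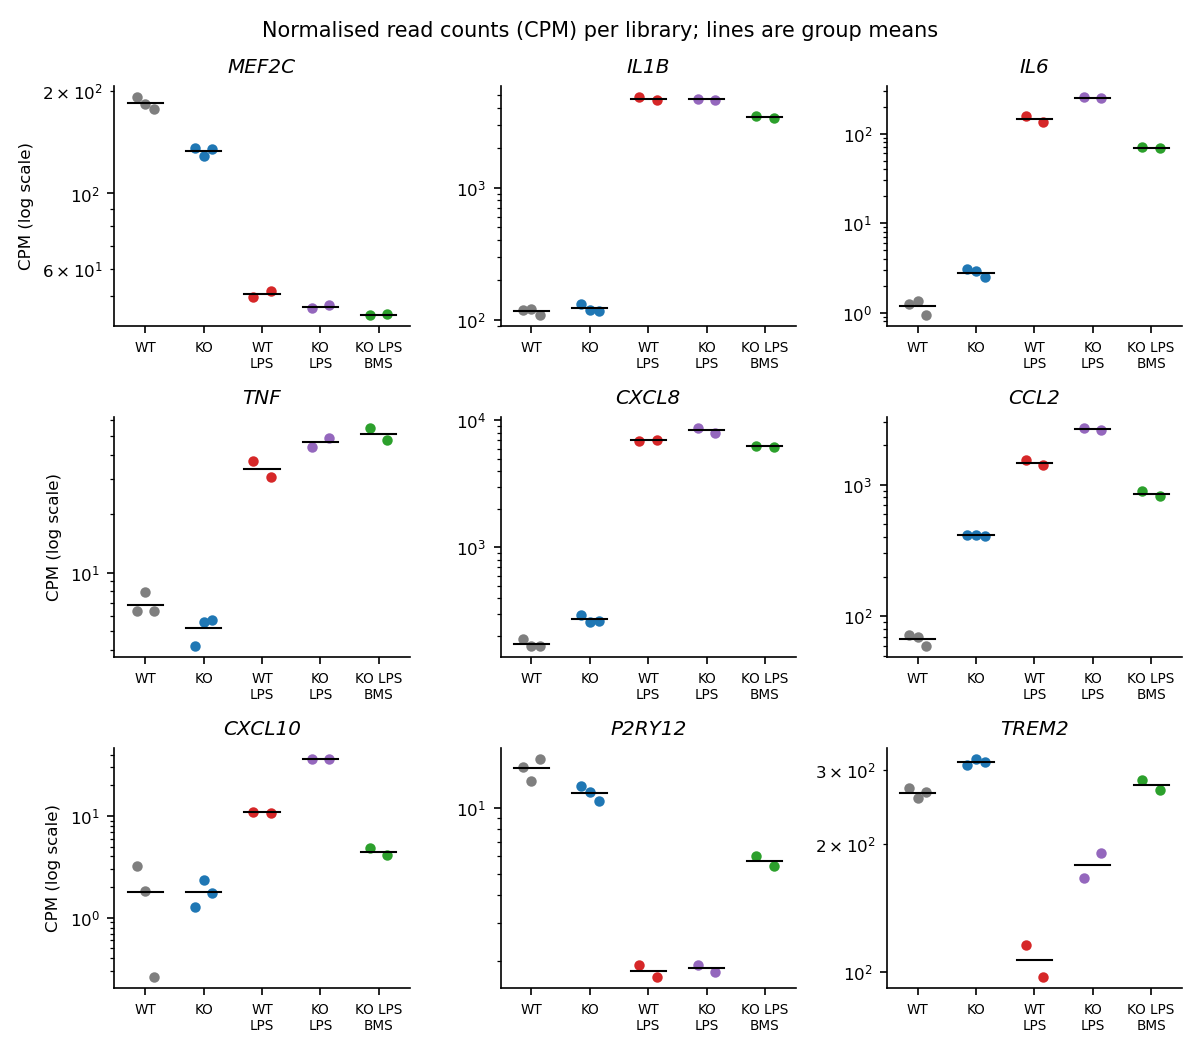
Normalised read counts (CPM, log axis) of 9 genes in each of the 12 libraries, with points for libraries and lines for group means (n = 3 without LPS, n = 2 with LPS). MEF2C averaged 184 CPM in WT, 133 CPM in KO and 50.6 CPM in WT with LPS, and IL6 averaged 252 CPM in KO with LPS and 69.6 CPM after addition of the compound.

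The comparison of KO with WT cells without LPS asked how iMGLs labelled as MEF2C knockout differed from unedited ones without the stimulus. The monocyte-attracting chemokines CCL13 and CCL2 rose in KO cells, CCL13 (ENSG00000181374, chromosome 17, 34356452 to 34358610) from 30.4 ± 2.28 to 215 ± 7.87 CPM (log2 fold change 2.82 ± 0.07, adjusted p = 7.83e-18) and CCL2 from 67.2 ± 6.91 to 411 ± 6.34 CPM (2.61 ± 0.06, adjusted p = 1.77e-16). The scavenger receptor gene MARCO rose from 12.4 ± 1.58 to 76.3 ± 1.15 CPM (2.62 ± 0.08, adjusted p = 3.78e-16), and SPP1, which encodes osteopontin, rose from 2614 ± 306 to 9314 ± 299 CPM (1.83 ± 0.07, adjusted p = 3.17e-09). Genes of antigen presentation on MHC class II were lower, and so was the CD1 gene CD1E. CD1E fell from 149.6 ± 5.51 to 23.5 ± 0.765 CPM (-2.67 ± 0.06, adjusted p = 7.83e-18), and CIITA, the master activator of MHC class II transcription, from 162 ± 10.3 to 39.3 ± 1.48 CPM (-2.04 ± 0.06, adjusted p = 2.06e-16). As lists tested by camera at the preset correlation, type I interferon-stimulated genes were higher (adjusted p = 0.0662 with an estimated correlation), and G1/S and G2/M genes were lower.

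Of the 16022 genes tested, 3463 (21.6%) were called, 1635 higher and 1828 lower in KO, and 590 of them changed by at least 2-fold, 399 higher and 191 lower. The other large rises were GALNT18 (2.69 ± 0.12), DLK1 (2.67 ± 0.17) and FCGR3B (2.60 ± 0.16), whose near-identical copy FCGR3A makes its count uncertain. The other large falls were HLA-DOA (-2.51 ± 0.09), the AP-1 gene FOSB (-2.34 ± 0.18), the transcription factor IRF4 (-2.32 ± 0.10), TGM5 (-2.29 ± 0.12) and PDK4 (-2.25 ± 0.09), a kinase that restrains pyruvate oxidation. Among the cytokine and microglial genes followed in every comparison, IL6 rose from 1.17 ± 0.215 to 2.8 ± 0.294 CPM (1.25 ± 0.18, adjusted p = 1.96e-05), CXCL8 by 0.64 ± 0.06, adjusted p = 3.49e-07, IL10 by 0.48 ± 0.11, adjusted p = 0.00329 and TREM2 by 0.24 ± 0.06, adjusted p = 0.00485. TNF (-0.40 ± 0.14, adjusted p = 0.056), IL1B (0.08 ± 0.05, adjusted p = 0.337) and CXCL10 (0.05 ± 0.60, adjusted p = 0.973) did not pass the test. The homeostatic gene P2RY12 changed by -0.37 ± 0.11, adjusted p = 0.0197, a call that ended without WT replicate 1 or 3 or KO replicate 2 or 3, and with DESeq2. Of the cell-cycle genes, CDKN1A changed by 0.73 ± 0.06, adjusted p = 2.09e-09 and MKI67 by -0.52 ± 0.07, adjusted p = 2.25e-05, while CDK2 did not pass (-0.08 ± 0.10, adjusted p = 0.638) and the call of CDK1 (-0.26 ± 0.07, adjusted p = 0.00542) ended without WT replicate 1.

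Among type I interferon-stimulated genes, 27 of 30 were higher, 0 lower and 3 not called, against 28 higher and 0 lower adjusted over the list alone. The median of 0.85 had camera adjusted p = 2.37e-22, and adjusted p = 0.0662 with an estimated correlation. CMPK2 changed by 1.10 ± 0.06 and IFI44 by 1.02 ± 0.07. For the chemokines, 12 of 21 were higher, 0 lower and 9 not called, against 13 higher and 1 lower adjusted over the list alone. The median of 0.60 had camera adjusted p = 9.2e-06, and adjusted p = 0.107 with an estimated correlation. In the list of MHC class I presentation, 11 of 20 were higher, 0 lower and 9 not called, against 12 higher and 0 lower adjusted over the list alone. The median of 0.26 had camera adjusted p = 2.51e-05, and adjusted p = 0.0912 with an estimated correlation. The transactivator NLRC5 changed by 1.02 ± 0.08 and HLA-B, a gene with near-identical relatives, by 0.34 ± 0.05. For MHC class II presentation, 12 of 15 were lower, 0 higher and 3 not called, against 12 lower and 1 higher adjusted over the list alone. The median of -1.27 had camera adjusted p = 1.09e-14, and adjusted p = 0.00993 with an estimated correlation. HLA-DPA1 went from 621 ± 11.8 to 226 ± 2.37 CPM (-1.46 ± 0.05, adjusted p = 3.78e-16). Counts of HLA genes are uncertain where reads fit several of them.

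Both lists of cell-cycle phases were lower in KO. For G1/S and DNA replication, 15 of 32 were lower, 0 higher and 17 not called, against 19 lower and 0 higher adjusted over the list alone. The median of -0.22 had camera adjusted p = 1.35e-05, and adjusted p = 0.0239 with an estimated correlation. The replication clamp PCNA changed by -0.31 ± 0.05 and the helicase subunit MCM4 by -0.32 ± 0.05. For G2/M and mitosis, 29 of 33 were lower, 0 higher and 4 not called, against 30 lower and 0 higher adjusted over the list alone. The median of -0.40 had camera adjusted p = 6.27e-15, and adjusted p = 0.0311 with an estimated correlation. NUSAP1 changed by -0.54 ± 0.06 and KIF11 by -0.61 ± 0.07, which act on the mitotic spindle. Immediate early and AP-1 genes were lower: 10 of 24 were lower, 4 higher and 10 not called, against 10 lower and 4 higher adjusted over the list alone. The median of -0.19 had camera adjusted p = 0.0203, and adjusted p = 0.537 with an estimated correlation. NR4A1 changed by -1.74 ± 0.11 and MYC by 0.63 ± 0.11. Glycolysis and HIF targets were higher: 11 of 26 were higher, 2 lower and 13 not called, against 13 higher and 2 lower adjusted over the list alone. The median of 0.19 had camera adjusted p = 0.00013, and adjusted p = 0.201 with an estimated correlation. SLC2A3 changed by 0.56 ± 0.05. In the list of phagocytosis and lysosome, 11 of 31 were higher, 3 lower and 17 not called, against 14 higher and 3 lower adjusted over the list alone. The median of 0.14 had camera adjusted p = 0.00148, and adjusted p = 0.146 with an estimated correlation. In the list of extracellular matrix and proteases, 10 of 19 were higher, 3 lower and 6 not called, against 10 higher and 3 lower adjusted over the list alone. The median of 0.30 had camera adjusted p = 0.000452, and adjusted p = 0.0484 with an estimated correlation. Dissociation and heat shock genes were higher: 7 of 13 were higher, 0 lower and 6 not called, against 10 higher and 0 lower adjusted over the list alone. The median of 0.31 had camera adjusted p = 4.28e-06, and adjusted p = 0.0118 with an estimated correlation.

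Markers of other cell types moved with the genotype. For monocytes and border macrophages, 14 of 18 were higher, 1 lower and 3 not called, against 14 higher and 3 lower adjusted over the list alone. The median of 0.64 had camera adjusted p = 2.78e-09, and adjusted p = 0.00993 with an estimated correlation. S100A9 went from 76.8 ± 1.18 to 258 ± 2.28 CPM (1.75 ± 0.05), and the coagulation factor gene F13A1 changed by 2.26 ± 0.10 and CCR2 by -0.46 ± 0.07. For granulocytic and mast cells, 10 of 17 were higher, 0 lower and 7 not called, against 10 higher and 0 lower adjusted over the list alone. The median of 0.47 had camera adjusted p = 3.4e-07, and adjusted p = 0.00993 with an estimated correlation. For endothelial cells, 4 of 10 were higher, 0 lower and 6 not called, against 6 higher and 0 lower adjusted over the list alone. The median of 0.61 had camera adjusted p = 0.00252, and adjusted p = 0.0484 with an estimated correlation. For erythroid and megakaryocytic cells, 4 of 9 were higher, 0 lower and 5 not called, against 5 higher and 0 lower adjusted over the list alone. The median of 0.40 had camera adjusted p = 0.0026, and adjusted p = 0.0484 with an estimated correlation. For astrocytes and oligodendrocytes, 4 of 10 were higher, 1 lower and 5 not called, against 4 higher and 1 lower adjusted over the list alone. The median of 0.33 had camera adjusted p = 0.0183, and adjusted p = 0.0912 with an estimated correlation. Mitochondrially encoded transcripts were lower: 2 of 13 were lower, 0 higher and 11 not called, against 4 lower and 0 higher adjusted over the list alone. The median of -0.22 had camera adjusted p = 0.00622, and adjusted p = 0.556 with an estimated correlation. The call ended without WT replicate 1 and with fry.

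Several microglial and signalling lists held members that moved in opposite directions and were not called as lists. Of 22 homeostatic microglial genes, 4 higher, 8 lower and 10 not called (camera adjusted p = 0.507), with the receptor MERTK at 0.99 ± 0.05 and CX3CR1 at -0.51 ± 0.06. Of 22 disease-associated microglial genes, 9 higher, 5 lower and 8 not called (0.218), with AXL at -0.71 ± 0.05 beside the rise of SPP1. Of 25 NF-kB genes, 4 higher, 8 lower and 13 not called (0.176), with the inhibitor TNFAIP3 at -0.85 ± 0.05. Pro-inflammatory cytokines (4 higher, 2 lower and 12 not called, camera adjusted p = 0.178), interferon-gamma-type genes (9 higher, 4 lower and 8 not called, 0.218), LPS receptor and TLR signalling (6 higher, 7 lower and 15 not called, 0.555) and anti-inflammatory genes (6 higher, 7 lower and 8 not called, 0.596) were not called. Neither were the inflammasome genes (1 higher, 4 lower and 13 not called, 0.904), whose mean had the other sign than the median and the test. MEF2 family and class IIa HDAC genes (2 higher, 2 lower and 8 not called, 0.507) included HDAC9 at -1.63 ± 0.11, and myeloid transcription factors (7 higher, 5 lower and 9 not called, 0.218) included KLF4 at 1.51 ± 0.15. CDKs, cyclins and CDK inhibitors (6 higher, 6 lower and 16 not called, 0.92, mean of the other sign than median and test) included CCND1 at 1.57 ± 0.07.

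Among metabolic and stress lists, camera did not call oxidative phosphorylation (2 higher, 0 lower and 22 not called, adjusted p = 0.104), cholesterol synthesis (5 higher, 4 lower and 14 not called, 0.507) or LXR targets (3 higher, 1 lower and 10 not called, 0.453). The same held for the unfolded protein and integrated stress response (5 higher, 5 lower and 12 not called, 0.846), oxidative stress and metal response (7 higher, 5 lower and 5 not called, 0.322), p53 targets (7 higher, 2 lower and 16 not called, 0.0675) and replication-dependent histones (2 higher, 0 lower and 6 not called, 0.0675). Kynurenine, prostaglandin and nitric oxide enzymes (3 higher, 3 lower and 10 not called, 0.507) were also not called. Of the remaining cell type markers, none of these lists was called by camera: pluripotent cells (3 higher, 0 lower and 3 not called, 0.447), mesenchymal cells (0 higher, 1 lower and 11 not called, 0.507), haematopoietic progenitors (3 higher, 1 lower and 5 not called, 0.322), neurons (3 higher, 0 lower and 3 not called, 0.0544) and lymphocytes (0 higher, 1 lower and 7 not called, 0.641). For lymphocytes the mean had the other sign than the median and the test.

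**Figure D2:**
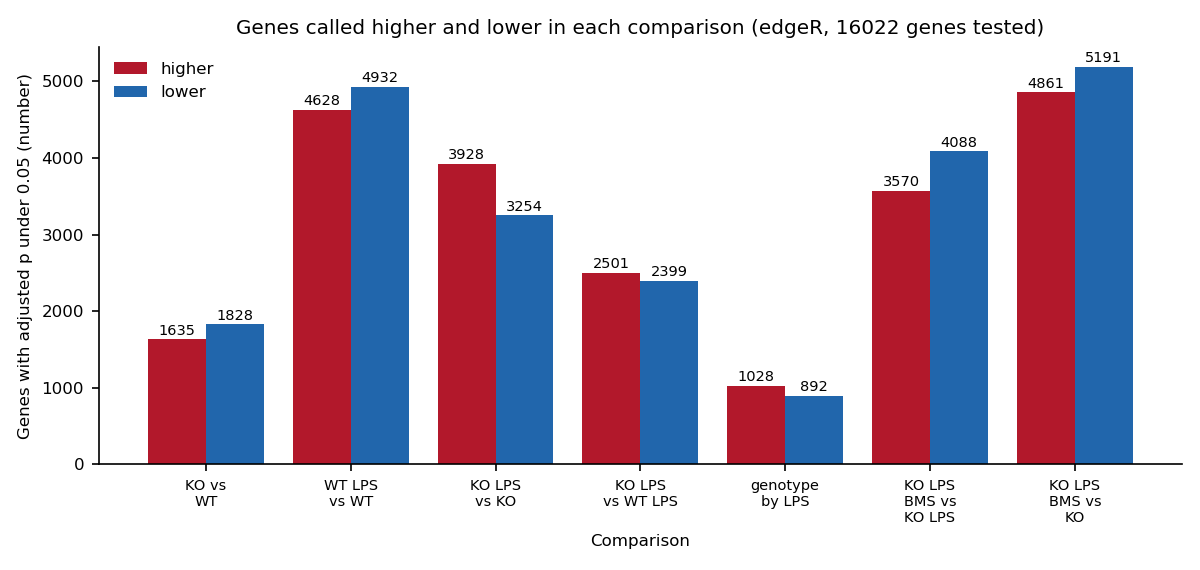
Number of genes called higher (red) and lower (blue) in each of the 7 comparisons, at an adjusted p under 0.05 from edgeR over 16022 genes. The bars run from 892 genes lower in the genotype by LPS interaction to 5191 genes lower in KO cells with LPS and BMS against KO cells without LPS.

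The comparison of WT cells with and without LPS gave the response of unedited iMGLs to the stimulus. The pro-inflammatory cytokine gene IL1B (ENSG00000125538, chromosome 2, 112829751 to 112836903) rose from 115 ± 6.97 to 4714 ± 199 CPM (log2 fold change 5.35 ± 0.06, adjusted p = 4.46e-25) and IL6 from 1.17 ± 0.215 to 146 ± 15 CPM (6.95 ± 0.11, adjusted p = 9.11e-23). SOD2, a mitochondrial superoxide dismutase, rose from 336 ± 7.91 to 12643 ± 389 CPM (5.23 ± 0.05, adjusted p = 4.84e-27). The homeostatic microglial receptor P2RY12 fell from 15.1 ± 1.72 to 1.81 ± 0.169 CPM (-3.05 ± 0.18, adjusted p = 1.24e-12), and MEF2C itself fell from 184 ± 7.86 to 50.6 ± 1.43 CPM (-1.86 ± 0.06, adjusted p = 9.97e-17). TREM2, a lipid receptor of microglia, fell by -1.31 ± 0.07, adjusted p = 4.09e-13.

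In this comparison 9560 genes (59.7%) were called, 4628 higher and 4932 lower, and 3226 changed by at least 2-fold, 1343 higher and 1883 lower. Scaling by library size only moved the median of all genes by -0.29 on the log2 scale and the share of calls that were higher from 48.4% to 26.7%, so the directions of small changes rest on the scaling. Genes near 0 without LPS are given as levels. The NF-kB inhibitor gene TNIP3 went from 0.034 ± 0.03 to 179 ± 20.6 CPM (adjusted p = 3.12e-23), ACOD1, the enzyme that makes itaconate, from 0.017 ± 0.03 to 46.6 ± 0.645 CPM (1.63e-17), and FFAR4 from 13 ± 1.69 to 0.064 ± 0.003 CPM (2.14e-14). LINC02605 had no count in WT cells and was at least 68.8-fold higher with LPS, against a floor of 3 counts per TMM-scaled library. The other large rises were PTX3 (8.39 ± 0.16), TNFAIP6 (8.35 ± 0.10) and LAD1 (7.42 ± 0.24). The other large falls were PDK4 (-5.20 ± 0.14), PRR15 (-5.12 ± 0.24), KIF26B (-4.93 ± 0.11), TMEM37 (-4.14 ± 0.36) and TNFRSF25 (-3.84 ± 0.22). Of the genes followed throughout, TNF changed by 2.30 ± 0.13, adjusted p = 1.05e-12, CXCL8 by 5.32 ± 0.07, adjusted p = 6.22e-20, CCL2 by 4.45 ± 0.07, adjusted p = 4.7e-21, IL10 by 2.99 ± 0.11, adjusted p = 2.03e-16 and CXCL10 by 2.61 ± 0.49, adjusted p = 0.0018. CDK1 (0.52 ± 0.07, adjusted p = 1.91e-06), CDK2 (0.54 ± 0.11, adjusted p = 0.000192) and CDKN1A (1.11 ± 0.06, adjusted p = 7.34e-13) were higher. The call of MKI67 (-0.24 ± 0.08, adjusted p = 0.0141) ended without WT replicate 2 or WT LPS replicate 1.

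The inflammatory lists rose with LPS in WT. For pro-inflammatory cytokines, 17 of 18 were higher, 0 lower and 1 not called, against 17 higher and 0 lower adjusted over the list alone. The median of 3.60 had camera adjusted p = 1.09e-08, and adjusted p = 0.0345 with an estimated correlation. For chemokines, 19 of 21 were higher, 2 lower and 0 not called, against 19 higher and 2 lower adjusted over the list alone. The median of 3.39 had camera adjusted p = 3.84e-09, and adjusted p = 0.091 with an estimated correlation. For NF-kB pathway and feedback genes, 23 of 25 were higher, 0 lower and 2 not called, against 23 higher and 0 lower adjusted over the list alone. The median of 2.58 had camera adjusted p = 1.37e-14, and adjusted p = 0.0576 with an estimated correlation. Interferon-gamma-type genes were higher as a list: 12 of 21 were higher, 6 lower and 3 not called, against 12 higher and 6 lower adjusted over the list alone. The median of 0.71 had camera adjusted p = 0.0228, and adjusted p = 0.139 with an estimated correlation. The checkpoint ligand CD274 changed by 3.86 ± 0.06 and CIITA by -1.40 ± 0.07. Type I interferon-stimulated genes were lower: 24 of 30 were lower, 0 higher and 6 not called, against 24 lower and 0 higher adjusted over the list alone. The median of -0.97 had camera adjusted p = 1.39e-06, and adjusted p = 0.34 with an estimated correlation. OAS1, a sensor of double-stranded RNA, changed by -1.78 ± 0.09. Of the homeostatic microglial genes, 13 of 22 were lower, 2 higher and 7 not called, against 14 lower and 2 higher adjusted over the list alone. The median of -0.33 had camera adjusted p = 0.00766, and adjusted p = 0.195 with an estimated correlation.

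Genes of G1/S and DNA replication fell with LPS in WT: 30 of 32 were lower, 0 higher and 2 not called, against 30 lower and 0 higher adjusted over the list alone. The median of -0.76 had camera adjusted p = 3.13e-08, and adjusted p = 0.0321 with an estimated correlation. G2/M and mitosis genes were not called as a list (camera adjusted p = 0.796). Some metabolic and stress lists rose. For glycolysis and HIF targets, 20 of 26 were higher, 2 lower and 4 not called, against 20 higher and 2 lower adjusted over the list alone. The median of 0.95 had camera adjusted p = 2.34e-06, and adjusted p = 0.168 with an estimated correlation. In the unfolded protein and integrated stress response, 16 of 22 were higher, 3 lower and 3 not called, against 16 higher and 3 lower adjusted over the list alone. The median of 0.93 had camera adjusted p = 0.000152, and adjusted p = 0.231 with an estimated correlation. For oxidative stress and metal response genes, 12 of 17 were higher, 1 lower and 4 not called, against 12 higher and 1 lower adjusted over the list alone. The median of 1.39 had camera adjusted p = 0.000325, and adjusted p = 0.091 with an estimated correlation. For extracellular matrix and proteases, 14 of 19 were higher, 4 lower and 1 not called, against 14 higher and 4 lower adjusted over the list alone. The median of 0.89 had camera adjusted p = 0.0116, and adjusted p = 0.139 with an estimated correlation. For kynurenine, prostaglandin and nitric oxide enzymes, 10 of 16 were higher, 6 lower and 0 not called, against 10 higher and 6 lower adjusted over the list alone. The median of 1.77 had camera adjusted p = 0.0324, and adjusted p = 0.139 with an estimated correlation. The calls of the interferon-gamma-type, matrix and kynurenine lists ended with a filter of 5 CPM in 2 libraries. None of the lists of other cell types was called.

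The comparison of KO cells with and without LPS gave the response of the knockout cells. IL1B rose from 122 ± 7.5 to 4650.5 ± 54 CPM (5.26 ± 0.06, adjusted p = 6.53e-25), IL6 from 2.8 ± 0.294 to 252 ± 6.99 CPM (6.49 ± 0.10, adjusted p = 4.73e-23) and CCL2 from 411 ± 6.34 to 2642 ± 61.5 CPM (2.68 ± 0.06, adjusted p = 8.03e-18). The T-cell-attracting chemokine gene CXCL10 rose from 1.8 ± 0.529 to 36.1 ± 0.233 CPM (4.30 ± 0.43, adjusted p = 5.77e-05). P2RY12 fell from 11.7 ± 0.887 to 1.86 ± 0.11 CPM (-2.64 ± 0.18, adjusted p = 4.69e-11), TREM2 from 312 ± 5.07 to 179 ± 17.3 CPM (-0.81 ± 0.07, adjusted p = 1.84e-09) and MEF2C from 133 ± 4.01 to 46.4 ± 0.618 CPM (-1.52 ± 0.06, adjusted p = 6.57e-15).

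There were 7182 genes called (44.8%), 3928 higher and 3254 lower, and 1790 changed by at least 2-fold, 1040 higher and 750 lower. Library size only moved the median of all genes by -0.25 and the share of calls that were higher from 54.7% to 25.5%, and upper-quartile factors gave 3052 higher and 4446 lower. TNIP3 went from 0.058 ± 0.006 to 139.8 ± 3.05 CPM (adjusted p = 1.69e-22) and ACOD1 from 0.037 ± 0.032 to 24.5 ± 1.66 CPM (1.38e-15). The other large rises were CCL20 (7.83 ± 0.10), PTX3 (7.68 ± 0.15), TNFAIP6 (6.65 ± 0.09) and CCL4 (6.61 ± 0.11), which has near-identical copies. The large falls were FFAR4 (-5.18 ± 0.24), PDK4 (-4.43 ± 0.19), CABLES1 (-3.44 ± 0.11), PRR15 (-3.36 ± 0.20), KIF26B (-3.15 ± 0.11) and TMEM37 (-2.89 ± 0.29). TNF (3.15 ± 0.13, adjusted p = 1.23e-14), CXCL8 (4.94 ± 0.07, adjusted p = 2.39e-19), IL10 (1.94 ± 0.11, adjusted p = 8.08e-13) and CDKN1A (0.52 ± 0.06, adjusted p = 3.76e-07) rose, and MKI67 did not pass (-0.03 ± 0.08, adjusted p = 0.749). The call of CDK1 (0.35 ± 0.07, adjusted p = 0.000461) ended with scaling by library size only. That of CDK2 (0.31 ± 0.11, adjusted p = 0.0305) ended without KO replicate 1 or 3 or KO LPS replicate 1, with library size only or upper-quartile factors, without the filter on low counts and with DESeq2.

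The lists called in KO cells with LPS included the inflammatory ones. For pro-inflammatory cytokines, 18 of 18 were higher, 0 lower and 0 not called, against 18 higher and 0 lower adjusted over the list alone. The median of 3.44 had camera adjusted p = 1.06e-12, and adjusted p = 0.0111 with an estimated correlation. For chemokines, 19 of 21 were higher, 1 lower and 1 not called, against 19 higher and 1 lower adjusted over the list alone. The median of 3.67 had camera adjusted p = 1.02e-12, and adjusted p = 0.0363 with an estimated correlation. For NF-kB genes, 25 of 25 were higher, 0 lower and 0 not called, against 25 higher and 0 lower adjusted over the list alone. The median of 2.54 had camera adjusted p = 1.83e-20, and adjusted p = 0.0231 with an estimated correlation. Lower, too, were the type I interferon-stimulated genes: 16 of 30 were lower, 1 higher and 13 not called, against 17 lower and 1 higher adjusted over the list alone. The median of -0.35 had camera adjusted p = 0.000898, and adjusted p = 0.544 with an estimated correlation. Homeostatic microglial genes were lower: 13 of 22 were lower, 2 higher and 7 not called, against 13 lower and 2 higher adjusted over the list alone. The median of -0.30 had camera adjusted p = 0.000327, and adjusted p = 0.0949 with an estimated correlation. G1/S and DNA replication genes were lower too: 26 of 32 were lower, 0 higher and 6 not called, against 30 lower and 0 higher adjusted over the list alone. The median of -0.53 had camera adjusted p = 3.13e-10, and adjusted p = 0.0111 with an estimated correlation. Immediate early and AP-1 genes were higher: 17 of 24 were higher, 1 lower and 6 not called, against 17 higher and 1 lower adjusted over the list alone. The median of 0.69 had camera adjusted p = 1.5e-05, and adjusted p = 0.275 with an estimated correlation. Of the 14 lists called, 5 held with an estimated correlation, and the other 7 called lists, all higher, are shown in the plot of list medians. No list of markers of other cell types was called in this comparison.

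The responses to LPS in the 2 genotypes shared most of their calls. A total of 6293 genes were called in both and in the same direction, 3461 higher and 2832 lower, where independent lists would share 1134.6 and 1001.7, and 37 were called in opposite directions. The genotype by LPS interaction, which tests the difference between the responses, called 1920 genes (12%). By the size of the estimates, whether or not a gene passed with LPS alone, the change was smaller in KO than in WT for 1767 of these (92%) and larger for 153. Of the 947 with a positive estimate in WT it was smaller in KO for 854, and of the 973 with a negative one for 913. Estimates had opposite signs in the genotypes for 251 of the 1920. The share of interaction calls that were positive was 53.5%, and 65.3% with scaling by library size only. DESeq2 size factors turned the balance, to 876 positive and 1140 negative. The count was 1212 without WT LPS replicate 2, 1162 without KO LPS replicate 2 and 3079 without KO LPS replicate 1.

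**Figure D3:**
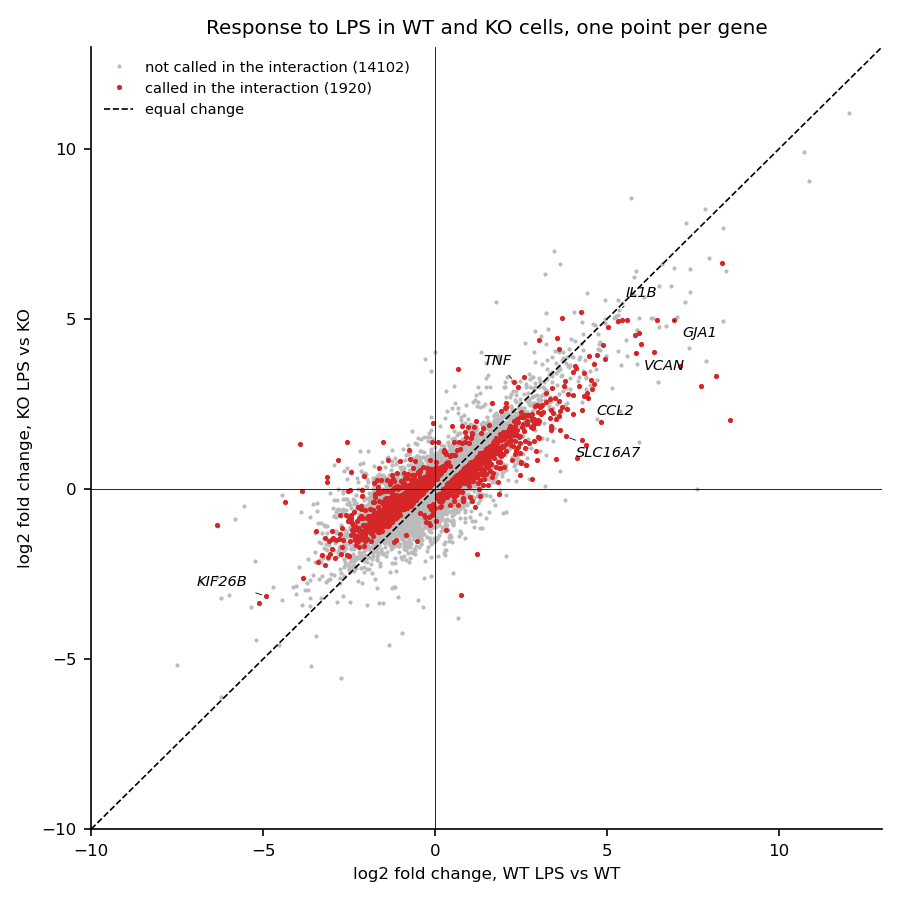
Log2 fold change with LPS in KO cells against that in WT cells, 1 point per gene, with the 1920 genes called in the interaction in red, the others in grey and a dashed line of equal change. CCL2 changed by 4.45 in WT and 2.68 in KO, and TNF by 2.30 in WT and 3.15 in KO.

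CCL2, already high in KO cells without LPS, responded less in KO (interaction -1.76 ± 0.09, adjusted p = 5.47e-10), as did IL10 (-1.05 ± 0.15, adjusted p = 8.73e-05) and CDKN1A (-0.59 ± 0.09, adjusted p = 0.000119). TNF responded more in KO (0.85 ± 0.19, adjusted p = 0.00484). TREM2 (0.51 ± 0.10, adjusted p = 0.0013) and MEF2C (0.34 ± 0.09, adjusted p = 0.0124) fell less in KO. The interaction of CXCL8 (-0.38 ± 0.09, adjusted p = 0.0118) was not called without WT LPS replicate 2 or KO LPS replicate 2. It did not pass the test for IL1B (-0.10 ± 0.08, adjusted p = 0.477), IL6 (-0.46 ± 0.20, adjusted p = 0.143), CXCL10 (1.69 ± 0.72, adjusted p = 0.185) or P2RY12 (0.41 ± 0.29, adjusted p = 0.391), nor for CDK1 (-0.17 ± 0.10, adjusted p = 0.325), CDK2 (-0.23 ± 0.16, adjusted p = 0.377) or MKI67 (0.20 ± 0.11, adjusted p = 0.259). Positive interaction terms prevailed among type I interferon-stimulated genes: 17 of 30 were higher, 0 lower and 13 not called, against 21 higher and 0 lower adjusted over the list alone. The median of 0.58 had camera adjusted p = 1.62e-08, and adjusted p = 0.756 with an estimated correlation. The other 4 lists called and the genes with the largest terms are given among the results for a closer look.

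The comparison of KO with WT cells in the presence of LPS asked how the stimulated knockout cells differed from stimulated unedited cells. CCL13 was at 38.2 ± 0.134 CPM in WT and 317 ± 37.9 CPM in KO (3.05 ± 0.08, adjusted p = 1.72e-16), and the interferon-induced antiviral genes IFIT1 and MX2 rose from 15.3 ± 0.164 to 95.8 ± 9.2 CPM (2.64 ± 0.21, adjusted p = 2.39e-05) and from 13.2 ± 1.71 to 81 ± 4 CPM (2.62 ± 0.17, adjusted p = 1.1e-06). IL6 was higher in KO, 146 ± 15 against 252 ± 6.99 CPM (0.79 ± 0.07, adjusted p = 4.48e-08), and so was CCL2 (0.85 ± 0.07, adjusted p = 2.26e-08). IL1B did not pass the test, with 4714 ± 199 CPM in WT and 4650.5 ± 54 CPM in KO (-0.02 ± 0.06, adjusted p = 0.835). LAMP3, a lysosomal membrane protein of mature dendritic cells, fell from 420.4 ± 2.88 to 67 ± 3.68 CPM (-2.65 ± 0.13, adjusted p = 8.25e-09) and CIITA from 61.3 ± 1.99 to 13.6 ± 0.24 CPM (-2.17 ± 0.09, adjusted p = 1.5e-13).

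In all, 4900 genes (30.6%) were called, 2501 higher and 2399 lower in KO, and 900 changed by at least 2-fold, 703 higher and 197 lower. The balance rested on the scaling, with 2878 higher and 1869 lower by library size only and 2243 and 2832 with DESeq2 size factors. The count was 3138 without WT LPS replicate 2 and 3005 without KO LPS replicate 2, and 2660 when the fit held only the libraries of the 2 groups. The other large rises were IBSP (4.16 ± 0.26), DLK1 (3.19 ± 0.25) and the chemokine CCL7 (2.79 ± 0.18). The other large falls were the chemokine receptor CCR7 (-2.80 ± 0.18), the glutamine transporter SLC38A1 (-2.67 ± 0.12), PRRX1 (-2.49 ± 0.32) and CD1E (-2.19 ± 0.09). TREM2 was higher in KO (0.75 ± 0.08, adjusted p = 1.6e-07), and IL10 (-0.57 ± 0.10, adjusted p = 0.000243) and CDK1 (-0.43 ± 0.08, adjusted p = 3e-04) were lower. The call of TNF (0.45 ± 0.12, adjusted p = 0.00686) ended without WT LPS replicate 2 or KO LPS replicate 2, and so did that of MKI67 (-0.32 ± 0.08, adjusted p = 0.00945), which ended also when only the libraries of the 2 groups were fitted. That of CXCL8 (0.26 ± 0.07, adjusted p = 0.0102) ended without either WT LPS replicate or KO LPS replicate 1. The call of CXCL10 (1.74 ± 0.39, adjusted p = 0.0117) ended without either WT LPS replicate and with DESeq2. MEF2C (-0.13 ± 0.07, adjusted p = 0.187), P2RY12 (0.04 ± 0.26, adjusted p = 0.926), CDK2 (-0.31 ± 0.12, adjusted p = 0.0539) and CDKN1A (0.14 ± 0.07, adjusted p = 0.144) did not pass the test.

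For type I interferon-stimulated genes in KO against WT with LPS, 28 of 30 were higher, 0 lower and 2 not called, against 28 higher and 0 lower adjusted over the list alone. The median of 1.57 had camera adjusted p = 1.83e-21, and adjusted p = 0.103 with an estimated correlation. For chemokines, 15 of 21 were higher, 2 lower and 4 not called, against 16 higher and 2 lower adjusted over the list alone. The median of 0.85 had camera adjusted p = 0.00049, and adjusted p = 0.28 with an estimated correlation. For MHC class II presentation, 13 of 15 were lower, 0 higher and 2 not called, against 14 lower and 0 higher adjusted over the list alone. The median of -1.36 had camera adjusted p = 7.78e-14, and adjusted p = 0.0343 with an estimated correlation. HLA-DRA went from 2454 ± 35.2 to 732 ± 8.64 CPM (-1.75 ± 0.06). For phagocytosis and lysosome, 18 of 31 were higher, 5 lower and 8 not called, against 18 higher and 7 lower adjusted over the list alone. The median of 0.28 had camera adjusted p = 0.00164, and adjusted p = 0.232 with an estimated correlation. For G2/M and mitosis, 26 of 33 were lower, 0 higher and 7 not called, against 26 lower and 0 higher adjusted over the list alone. The median of -0.40 had camera adjusted p = 6.77e-11, and adjusted p = 0.0855 with an estimated correlation. Markers of other cell types moved here as well. For endothelial cells, 7 of 10 were higher, 0 lower and 3 not called, against 7 higher and 0 lower adjusted over the list alone. The median of 1.17 had camera adjusted p = 0.00049, and adjusted p = 0.0443 with an estimated correlation. For granulocytic and mast cells, 11 of 17 were higher, 1 lower and 5 not called, against 11 higher and 1 lower adjusted over the list alone. The median of 0.47 had camera adjusted p = 0.000261, and adjusted p = 0.0443 with an estimated correlation. For monocytes and border macrophages, 11 of 18 were higher, 2 lower and 5 not called, against 13 higher and 2 lower adjusted over the list alone. The median of 0.48 had camera adjusted p = 0.000234, and adjusted p = 0.0443 with an estimated correlation. For erythroid and megakaryocytic cells, 5 of 9 were higher, 0 lower and 4 not called, against 5 higher and 0 lower adjusted over the list alone. The median of 0.88 had camera adjusted p = 0.0119, and adjusted p = 0.103 with an estimated correlation. The call ended without the filter on low counts. Mitochondrially encoded transcripts were lower: 7 of 13 were lower, 0 higher and 6 not called, against 11 lower and 0 higher adjusted over the list alone. The median of -0.37 had camera adjusted p = 0.00136, and adjusted p = 0.634 with an estimated correlation. Pro-inflammatory cytokines (10 higher, 1 lower and 7 not called, camera adjusted p = 0.0849) and NF-kB genes (3 higher, 5 lower and 17 not called, 0.469) were not called as lists.

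Of the genes called between KO and WT without LPS, 1817 were called in the same direction with LPS, 937 higher and 880 lower, where independent lists would share 255.2 and 273.7. Another 169 had opposite directions. The 2 comparisons had no library in common.

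**Figure D4:**
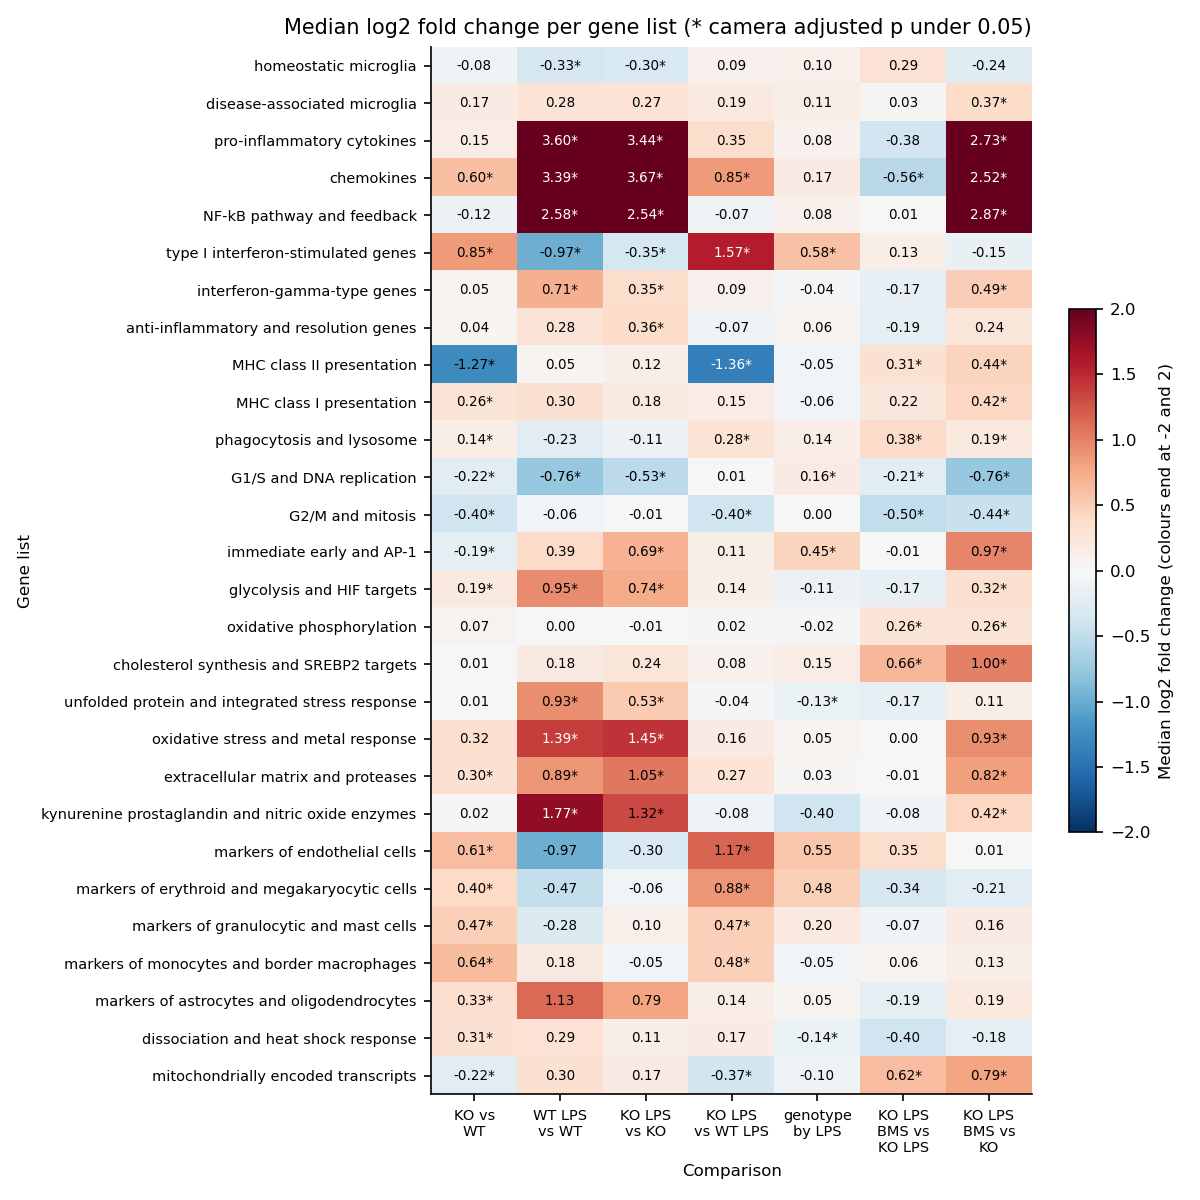
Median log2 fold change of the gene lists (rows) that camera called in at least 1 of the 7 comparisons (columns), with an asterisk at an adjusted p under 0.05. The median of type I interferon-stimulated genes was 0.85 in KO against WT and -0.97 with LPS in WT, and scaling by library size only flips the sign of some medians near 0.

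The comparison of KO cells with LPS and BMS against KO cells with LPS asked what the compound changed in stimulated knockout cells. IL6 fell from 252 ± 6.99 to 69.6 ± 1.46 CPM (-1.86 ± 0.08, adjusted p = 6.02e-14), CCL2 from 2642 ± 61.5 to 849.6 ± 51 CPM (-1.64 ± 0.07, adjusted p = 9.46e-13) and CXCL10 from 36.1 ± 0.233 to 4.46 ± 0.486 CPM (-3.02 ± 0.45, adjusted p = 0.000726). IL1B fell from 4650.5 ± 54 to 3417 ± 84.7 CPM (-0.44 ± 0.06, adjusted p = 2.36e-06), and TNF did not pass the test, with 46.4 ± 3.25 CPM before and 51.2 ± 5.2 CPM with the compound (0.14 ± 0.12, adjusted p = 0.342). TREM2 rose from 179 ± 17.3 to 276 ± 10.4 CPM (0.63 ± 0.07, adjusted p = 4.63e-07) and P2RY12 from 1.86 ± 0.11 to 5.7 ± 0.411 CPM (1.61 ± 0.22, adjusted p = 2.74e-06). INSIG1, a sterol-regulated gene, rose from 283 ± 7.49 to 780.2 ± 7.38 CPM (1.46 ± 0.06, adjusted p = 1.51e-14). Without WT cells given the compound or KO cells given it without LPS, the data do not show whether these changes depend on the genotype or on LPS.

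The compound comparison called 7658 genes (47.8%), 3570 higher and 4088 lower, and 1884 changed by at least 2-fold, 629 higher and 1255 lower. Library size only gave 2868 higher and 4865 lower, and DESeq2 size factors turned the balance, to 3847 and 3819. The large rises were the adhesion gene ICAM5, from 5.83 ± 2.4 to 68.8 ± 9.15 CPM (3.57 ± 0.20), the calcium-dependent kinase CAMK4 (3.14 ± 0.32), PCDH18 (3.13 ± 0.24) and CCDC17 (3.02 ± 0.19). The antisense genes ARHGAP31-AS1 (3.97 ± 0.29) and PSMD6-AS2 (2.50 ± 0.21) rose and PRKAG2-AS2 fell (-3.22 ± 0.18). They overlap other genes, and the strand setting of the counts is not given in the sources used here, so which gene their reads came from is uncertain. The other large falls were MIR223HG (-3.61 ± 0.09), the host transcript of a myeloid microRNA, ACOD1 (-3.56 ± 0.21), PPP1R10 (-3.07 ± 0.09) and the immediate early gene EGR1 (-2.94 ± 0.21). CXCL8 (-0.42 ± 0.07, adjusted p = 0.000106), IL10 (-0.63 ± 0.11, adjusted p = 7.29e-05), CDK1 (-0.48 ± 0.08, adjusted p = 6.71e-05) and CDKN1A (-0.33 ± 0.07, adjusted p = 0.000375) fell. MEF2C (-0.08 ± 0.07, adjusted p = 0.395), CDK2 (0.00 ± 0.12, adjusted p = 0.999) and MKI67 (-0.16 ± 0.09, adjusted p = 0.137) did not pass the test.

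Cholesterol synthesis and SREBP2 targets rose with the compound: 22 of 23 were higher, 0 lower and 1 not called, against 22 higher and 0 lower adjusted over the list alone. The median of 0.66 had camera adjusted p = 1.01e-10, and adjusted p = 0.0631 with an estimated correlation. MSMO1 went from 107 ± 6.54 to 272 ± 1.86 CPM (1.35 ± 0.06). In the list of phagocytosis and lysosome, 22 of 31 were higher, 4 lower and 5 not called, against 22 higher and 4 lower adjusted over the list alone. The median of 0.38 had camera adjusted p = 0.000256, and adjusted p = 0.302 with an estimated correlation. The cholesterol exporter NPC1 changed by 0.76 ± 0.06 and LAMP1 by 0.63 ± 0.06. For MHC class II presentation, 9 of 15 were higher, 0 lower and 6 not called, against 10 higher and 0 lower adjusted over the list alone. The median of 0.31 had camera adjusted p = 0.00116, and adjusted p = 0.302 with an estimated correlation. For oxidative phosphorylation, 14 of 24 were higher, 0 lower and 10 not called, against 14 higher and 1 lower adjusted over the list alone. The median of 0.26 had camera adjusted p = 0.00246, and adjusted p = 0.409 with an estimated correlation. Mitochondrially encoded transcripts were higher: 12 of 13 were higher, 0 lower and 1 not called, against 12 higher and 0 lower adjusted over the list alone. The median of 0.62 had camera adjusted p = 0.000155, and adjusted p = 0.654 with an estimated correlation.

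Mitotic genes fell with the compound: for G2/M and mitosis, 24 of 33 were lower, 0 higher and 9 not called, against 24 lower and 0 higher adjusted over the list alone. The median of -0.50 had camera adjusted p = 9.07e-07, and adjusted p = 0.302 with an estimated correlation. NUSAP1 changed by -1.06 ± 0.08 and KIF20A by -1.21 ± 0.09. For G1/S and DNA replication, 15 of 32 were lower, 4 higher and 13 not called, against 15 lower and 4 higher adjusted over the list alone. The median of -0.21 had camera adjusted p = 0.0368, and adjusted p = 0.302 with an estimated correlation. The call ended without KO LPS replicate 1 or KO LPS BMS replicate 2 and with a filter of 5 CPM in 2 libraries. For chemokines, 13 of 21 were lower, 2 higher and 6 not called, against 13 lower and 2 higher adjusted over the list alone. The median of -0.56 had camera adjusted p = 0.0368, and adjusted p = 0.632 with an estimated correlation. CXCL5 changed by -1.24 ± 0.08 and CXCL16 by 0.53 ± 0.07. The call ended without KO LPS BMS replicate 2 and with library size only. No list of markers of other cell types was called.

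Other lists held members that changed in both directions and were not called. Pro-inflammatory cytokines (3 higher, 9 lower and 6 not called, camera adjusted p = 0.247) included OSM at -1.49 ± 0.12, INHBA at 1.74 ± 0.07 and IL18 at 0.86 ± 0.08. NF-kB genes (7 higher, 8 lower and 10 not called, 0.925, median and mean of different sign) included TNIP3 at -1.70 ± 0.09 and BCL2A1 at 0.97 ± 0.07. Homeostatic microglial genes (13 higher, 5 lower and 4 not called, 0.0993) included MERTK at 1.36 ± 0.07 and P2RY13 at -1.72 ± 0.09. Interferon-gamma-type genes (4 higher, 9 lower and 8 not called, 0.568) included the transcription factor IRF8, which rose from 215 ± 15.1 to 796 ± 27.4 CPM (1.89 ± 0.06),. CDKs, cyclins and CDK inhibitors (7 higher, 9 lower and 12 not called, 0.875) included CCNT1, a partner of CDK9, at 1.12 ± 0.07. Type I interferon-stimulated genes (10 higher, 7 lower and 13 not called, 0.428) were not called either.

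The 4628 genes that LPS raised in WT, a set defined on libraries that the compound comparison does not use, had a median log2 fold change of -0.03 with the compound (camera adjusted p = 0.987, adjusted over the pair of sets), with 1487 lower and 1344 higher. The 4932 that LPS lowered in WT had a median of -0.02 (camera adjusted p = 0.987), with 1075 higher and 1245 lower. Limited to at least 2-fold in WT, the raised set of 1343 genes had a median of -0.20, with 61.1% below 0, 512 called lower and 284 higher (camera adjusted p = 0.0754). The lowered set of 1883 genes had a median of -0.02 (camera adjusted p = 0.642). Against KO cells without LPS, those 1343 genes had a median of 1.35 with LPS and 1.19 with LPS and the compound, and those 1883 genes had medians of -0.81 and -0.89.

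Among genes called with LPS in KO, 2120 were called in the opposite direction with the compound and 2021 in the same direction. The opposite calls divided into 1301 higher with LPS and lower with the compound, and 819 lower and then higher, where independent lists would share 1002.2 and 725.1. For the same direction independent lists would share 1705.5, so calls in that direction were in excess as well. The 2 comparisons share both KO LPS libraries, so part of the excess may come from these. In 10 simulations without any effect they gave a mean of 0.1 and at most 1 such gene. Few genes can be called there, so this cannot size that part. Signs were opposite in 68.5% of genes (51.2% observed), with a covariance of -0.0364 (-0.102 observed). Of the genes called between KO and WT with LPS, 1373 moved in the opposite direction with the compound and 1476 in the same direction, where independent lists would share 1169.4 in the same direction. Opposite calls were 686 and 687, against 638.1 and 534.5 for independent lists. Here too both KO LPS libraries are shared and may give part of the excess, and the covariance was -0.042 against a simulated -0.036. The count of 1373 was 751 without KO LPS replicate 2. Of the genes called between KO and WT without LPS, which shares no library, 979 were opposite (499 and 480, against 417.2 and 407.3 for independent lists) and 1078 were in the same direction, against 830.7. The excess of opposite calls was thus not particular to that direction in these comparisons.

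The comparison of KO cells with LPS and BMS against KO cells without either treatment gave the net change with both treatments. IL1B stayed above its level without LPS, 122 ± 7.5 against 3417 ± 84.7 CPM (4.81 ± 0.06, adjusted p = 4.49e-24), and so did IL6, 2.8 ± 0.294 against 69.6 ± 1.46 CPM (4.64 ± 0.10, adjusted p = 4.94e-20), and CCL2 (1.05 ± 0.06, adjusted p = 1.99e-11). CXCL10 did not pass the test (1.28 ± 0.59, adjusted p = 0.0909). P2RY12 stayed below its level without LPS, 11.7 ± 0.887 against 5.7 ± 0.411 CPM (-1.04 ± 0.15, adjusted p = 2.8e-06). MEF2C was lower (-1.60 ± 0.06, adjusted p = 2.45e-15).

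This net comparison called 10052 genes (62.7%), 4861 higher and 5191 lower, of which 3627 changed by at least 2-fold. Library size only moved the median of all genes by -0.34 and the share of calls that were higher from 48.4% to 26.1%. IL12B, which had no count in KO cells without LPS, was at least 60.6-fold higher, against a floor of 3 counts per TMM-scaled library. With LPS alone it was at least 14.1-fold higher, and its lowest level was 2.74 CPM in KO LPS against 11.7 CPM in KO LPS BMS. TNIP3 stood at 42.9 ± 3.46 CPM. The other large rises were CCL20 (7.12 ± 0.10), TNFAIP6 (6.32 ± 0.09) and the near-identical pair HCAR2 (6.61 ± 0.24) and HCAR3 (6.10 ± 0.30). The large falls were PDK4 (-5.08 ± 0.21), FFAR4 (-4.27 ± 0.22), CRACDL (-3.83 ± 0.26), HTR7P1 (-3.70 ± 0.27), CXCR2 (-3.42 ± 0.16) and IRAG1 (-3.31 ± 0.20). TNF (3.29 ± 0.13, adjusted p = 4.04e-15), CXCL8 (4.52 ± 0.07, adjusted p = 4.91e-19) and IL10 (1.31 ± 0.11, adjusted p = 1.04e-09) were higher, and CDK1 did not pass (-0.12 ± 0.08, adjusted p = 0.166). CDK2 (0.31 ± 0.11, adjusted p = 0.0231) and CDKN1A (0.19 ± 0.06, adjusted p = 0.0137) were higher, but with library size only the direction turned, to -0.03 and -0.15. These 2 calls also ended without KO replicate 1 or KO LPS BMS replicate 1 and with upper-quartile factors. The call of TREM2 (-0.18 ± 0.07, adjusted p = 0.0251) ended without KO replicate 2 or 3 or KO LPS BMS replicate 2 and with DESeq2, and that of MKI67 (-0.19 ± 0.08, adjusted p = 0.0393) ended without WT replicate 1 or any 1 KO or KO LPS BMS replicate and with DESeq2.

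The lists called in this net comparison again included pro-inflammatory cytokines, of which 14 of 18 were higher, 2 lower and 2 not called, against 14 higher and 2 lower adjusted over the list alone. The median of 2.73 had camera adjusted p = 1.66e-06, and adjusted p = 0.0461 with an estimated correlation. For chemokines, 17 of 21 were higher, 0 lower and 4 not called, against 17 higher and 0 lower adjusted over the list alone. The median of 2.52 had camera adjusted p = 6.25e-09, and adjusted p = 0.0561 with an estimated correlation. For NF-kB genes, 25 of 25 were higher, 0 lower and 0 not called, against 25 higher and 0 lower adjusted over the list alone. The median of 2.87 had camera adjusted p = 3.19e-15, and adjusted p = 0.0461 with an estimated correlation. For cholesterol synthesis and SREBP2 targets, 20 of 23 were higher, 1 lower and 2 not called, against 20 higher and 1 lower adjusted over the list alone. The median of 1.00 had camera adjusted p = 9.38e-08, and adjusted p = 0.0461 with an estimated correlation. Disease-associated microglial genes were higher: 14 of 22 were higher, 3 lower and 5 not called, against 14 higher and 3 lower adjusted over the list alone. The median of 0.37 had camera adjusted p = 0.00144, and adjusted p = 0.315 with an estimated correlation. G1/S and DNA replication genes were lower: 29 of 32 were lower, 0 higher and 3 not called, against 29 lower and 0 higher adjusted over the list alone. The median of -0.76 had camera adjusted p = 2.85e-08, and adjusted p = 0.0302 with an estimated correlation. G2/M and mitosis genes were lower too: 24 of 33 were lower, 1 higher and 8 not called, against 24 lower and 1 higher adjusted over the list alone. The median of -0.44 had camera adjusted p = 1.7e-05, and adjusted p = 0.205 with an estimated correlation. For mitochondrially encoded transcripts, 13 of 13 were higher, 0 lower and 0 not called, against 13 higher and 0 lower adjusted over the list alone. The median of 0.79 had camera adjusted p = 0.00021, and adjusted p = 0.365 with an estimated correlation. Of the 18 lists called, 4 held with an estimated correlation. The calls of 4 lists, each higher here, ended with library size only: MHC class II (11 higher, 2 lower and 2 not called, camera adjusted p = 0.0259), MHC class I (14 higher, 3 lower and 3 not called, 0.0463), phagocytosis and lysosome (16 higher, 3 lower and 12 not called, 0.011) and oxidative phosphorylation (13 higher, 1 lower and 10 not called, 0.0171), with adjusted p = 0.313, 0.331, 0.308 and 0.315 with an estimated correlation, and the medians of the last pair then turned negative. The other 6 called lists, all higher, are shown in the plot of list medians. Of these, glycolysis and HIF targets had a median of -0.01 with library size only. The MHC class I call also ended without any 1 KO replicate or without KO LPS BMS replicate 1, and the oxidative phosphorylation call without KO LPS BMS replicate 1. Type I interferon-stimulated genes (4 higher, 14 lower and 12 not called, 0.208) and homeostatic microglial genes (5 higher, 11 lower and 6 not called, 0.208) were not called.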

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

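The difference between the responses to LPS in KO and WT, tested by the interaction, picked out the results listed here. The tests chosen after the result was seen are those of endotoxin acting as the added LPS did, of near-identical HLA genes, of the relation with LPS alone and of short-lived transcripts.

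The interaction called 1920 genes, 1028 with a positive and 892 with a negative term. With LPS in KO less that in WT as the sign, the median term of the type I interferon-stimulated genes was 0.58 (adjusted p = 0.756 with an estimated correlation). For G1/S and DNA replication 8 of 32 were higher, 0 lower and 24 not called, against 9 higher and 0 lower adjusted over the list alone. The median of 0.16 had camera adjusted p = 0.0293, and adjusted p = 0.567 with an estimated correlation, and the call ended without KO replicate 3, WT LPS replicate 1 or KO LPS replicate 1 and with DESeq2 size factors. For immediate early and AP-1 genes 9 of 24 were higher, 2 lower and 13 not called, against 11 higher and 3 lower adjusted over the list alone. The median of 0.45 had camera adjusted p = 0.0293, and adjusted p = 0.772 with an estimated correlation, and the call ended without WT LPS replicate 2 or KO LPS replicate 2 and with fry. In the unfolded protein and integrated stress response 5 of 22 were lower, 1 higher and 16 not called, against 5 lower and 1 higher adjusted over the list alone. The median of -0.13 had camera adjusted p = 0.0293, and adjusted p = 0.772 with an estimated correlation, and the call ended without WT LPS replicate 1 or KO LPS replicate 1 and with a filter of 5 CPM. Among dissociation and heat shock genes 4 of 13 were lower, 0 higher and 9 not called, against 4 lower and 0 higher adjusted over the list alone. The median of -0.14 had camera adjusted p = 0.0293, and adjusted p = 0.567 with an estimated correlation, and the call ended without KO replicate 3, WT LPS replicate 1 or KO LPS replicate 1 and with a filter of 5 CPM.

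Among the genes followed in every comparison the interaction was called for MEF2C (0.34), TNF (0.85), CXCL8 (-0.38, not without WT LPS replicate 2 or KO LPS replicate 2), CCL2 (-1.76), IL10 (-1.05), TREM2 (0.51) and CDKN1A (-0.59). The largest positive terms were SHC3 (1.82 ± 0.40, adjusted p = 0.00468), KIF26B (1.78 ± 0.17, adjusted p = 5.96e-07), TGM5 (1.77 ± 0.30, adjusted p = 0.000403), PRR15 (1.76 ± 0.39, adjusted p = 0.00525), GRAMD1B (1.63 ± 0.17, adjusted p = 1.93e-06) and JAG1 (1.61 ± 0.11, adjusted p = 2.56e-09). The call of PRR15 ended without WT LPS replicate 2 or KO LPS replicate 2. The largest negative terms were CCN2 (-2.32 ± 0.58, adjusted p = 0.0119), SLC16A7 (-2.25 ± 0.24, adjusted p = 2.22e-06), GJA1 (-1.98 ± 0.18, adjusted p = 2.72e-07), PLS3 (-1.92 ± 0.16, adjusted p = 9.05e-08), CCR7 (-1.90 ± 0.31, adjusted p = 0.000307) and VCAN (-1.84 ± 0.19, adjusted p = 1.2e-05). The call of CCN2 ended without KO replicate 1.

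Type I interferon-stimulated genes were higher in KO than in WT without LPS, at the preset but not the estimated correlation (adjusted p = 0.0662). Without any 1 of the 6 libraries at least 25 members were still called higher, which argues against 1 deviating library. Endotoxin acting as the added LPS did would lower these genes (median with LPS in WT -0.97). A trace could act differently from the dose and time used. Of the 100 genes that LPS raised most firmly in WT, 47 were higher and 25 lower in KO. For chemokines these were 12 and 0, for NF-kB genes 4 and 8, and for all 16022 genes 1635 and 1828. These counts cannot tell traces of endotoxin from the genotype. A genotype effect, which every KO culture shares, stays open as a hypothesis.

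MHC class II genes, and of the CD1 genes CD1E, were lower in KO than in WT without LPS. The 9 class II list members that are not near copies of other genes had a median of -1.0, so reads shared between near-identical HLA genes may add to the change but do not account for it. Fewer dendritic-like cells in the KO cultures is a candidate explanation: of 18 dendritic cell markers, 7 were lower, 1 higher and 6 above 0, with a median of -0.36. Without CCL22 and FLT3, which stand in lists already tested, 6 of 16 were lower and the median was -0.36. The most abundant were PLD4 at 296 CPM (-0.55, adjusted p = 0.058) and CLEC10A at 101 CPM (-0.83), and a change of cell types and a change within cells of 1 type cannot be told apart.

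Genes annotated with 1 exon were lower with the compound than other genes. The pattern, first written for 1 or 2 exons, was narrowed after the medians by exon number were seen (-0.23 and 0.01). The gap in medians was -0.20 (95% bootstrap interval over genes, not cultures, -0.31 to -0.08, 458 against 12656). After regression on GC content and transcript length it was -0.19 (-0.30 to -0.10), which argues against these as the whole cause. A loss of all short-lived transcripts would lower immediate early and AP-1 genes as a group, but 9 of 24 were higher and 9 lower. With LPS alone the gap was -0.11 (-0.16 to -0.03) in WT and -0.04 (-0.10 to 0) in KO. Both sides of the compound comparison had LPS, so this cannot decide the cause, and no other explanation was tested.

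Of the 10 splits of the 6 libraries without LPS into 3 and 3, the real one called 3463 genes by edgeR and the others 0. At an unadjusted p under 0.05 the counts were 5130 and 206 to 463. Mixed genotypes widen the spread in the others, so their low counts decide nothing. With 10 splits no exact p falls under 0.1.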

How the results depend on the processing

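The exchange of KO LPS replicate numbers was chosen after the data were seen. Named genes kept direction and side of the threshold in 20078 of the recomputed values, 386 no longer passed, 26 passed only then and 5 changed sign, all with library size only: LIN28B in WT LPS vs WT (-0.05), and in KO LPS BMS vs KO CDK2 (-0.031), CDKN1A (-0.152), STAT2 (-0.067) and CKS1B (-0.124). List calls held in 1575 values, mostly refits without 1 library, and ended in 101. An estimated correlation kept 24 and lost 60. No camera direction turned, though some medians near 0 did with library size only. Counts, overlaps, MEF2C and the medians of the LPS sets kept their value or side in 311 values, and 17 counts or overlaps moved by more than 1.5 times.

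In every comparison but KO LPS BMS vs KO, which direction held more calls depended on the scaling. With at least 2-fold required, the calls were 590, 3226, 1790, 900, 237, 1884 and 3627, in the order of the comparisons in the processing section, by construction. At an adjusted p under 0.01 they were 2250 in KO vs WT, 3049 in KO LPS vs WT LPS and 962 in the interaction. With only the libraries of the 2 groups, KO LPS vs WT LPS called 2660; the cause was not tested. The set raised at least 2-fold by LPS in WT had a median of -0.203 with the compound. Its unadjusted camera p was then under 0.05, while adjustment over the pair of sets, added after the data were seen, left it above; the cause was not tested. The replicate numbers gave little sign of pairing (residual correlations of 21 same-number pairs from -0.143 to 0.103). With the replicate number as a block, the calls were 3091, 8973, 6562, 4454, 1543, 7379 and 9551, and with the KO LPS numbers exchanged 4651 in KO LPS vs WT LPS and 7514 in KO LPS BMS vs KO LPS.

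Leaving out 1 library at a time gave 2593 to 3857 calls in KO vs WT, 8052 to 9949 in WT LPS vs WT, 6037 to 7375 in KO LPS vs KO, 3005 to 5549 in KO LPS vs WT LPS, 1162 to 3079 in the interaction, 6242 to 7869 in KO LPS BMS vs KO LPS and 8646 to 10470 in KO LPS BMS vs KO. A group left with 1 library was assumed to vary like the others. MEF2C in KO vs WT ranged from -0.495 to -0.433. Overlaps ranged from 1749 to 2202 (KO LPS vs KO with the compound), 751 (without KO LPS replicate 2) to 1745 (KO LPS vs WT LPS with the compound), 733 to 1050 (KO vs WT with the compound), 1461 to 1867 (KO vs WT with KO LPS vs WT LPS) and 5164 to 6286 (both LPS responses). The medians of the LPS sets with the compound ranged from -0.046 to 0.022 and from -0.053 to 0.056. Why KO LPS vs WT LPS and the interaction ranged so widely was not tested. The 2 alternatives written for normalised values were not run, since the table holds counts. In simulated data the tests missed more 1.5-fold than 4-fold changes.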

Other observations

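The dendritic cell markers and the grouping by exon number were chosen after the results on MHC class II and on the compound were seen.

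Several markers of conventional dendritic cells were lower in KO than in WT without LPS (log2 fold changes, edgeR). They included CCL17 (-2.76, adjusted p = 1.11e-06, mean 1.22 CPM) and CD207 (-1.29, 4.12e-06, 4.26 CPM). Others were PKIB (-0.68, 9.23e-08), CADM1 (-0.48, 5.17e-07) and ZBTB46 (-0.42, 0.00221). FLT3 was also lower (-1.30, adjusted p = 0.0263, mean 0.54 CPM) and FSCN1 higher (0.90, 0.0392). CCL22 (0.05, adjusted p = 0.664), CD83 (0.02, 0.866), BATF3 (0.06, 0.878), WDFY4 (-0.07, 0.784) and SNX22 (-0.06, 0.892) did not pass, among others. Within the class II pathway the cathepsin CTSS (-0.05, adjusted p = 0.532) and the costimulatory ligand CD86 (-0.07, adjusted p = 0.372) did not pass either, beside the falls of CD74 (-1.30, adjusted p = 1.11e-07) and HLA-DMB (-0.59, adjusted p = 4.18e-08).

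With the compound, 157 of the 458 genes annotated with a single exon were called lower and 88 higher. The share called lower was 34.3% with 1 exon, 25.9% with 2, 21.9% with 3 to 4, 24.3% with 5 to 9 and 31.5% with 10 or more, so it did not fall steadily with exon number. At least 2-fold falls were called in 15.7% of the genes with 1 exon, 9.6% of those with 2, 6.6% with 3 to 4, 6.3% with 5 to 9 and 6.1% with 10 or more.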
